A study of Mus musculus with 5 samples.

How the data were processed

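Total RNA was extracted with a column kit from GFP-positive cells sorted from trypsin-dissociated lungs of SPC-GFP pups on postnatal day 2, per the labels' protocols. It was amplified and biotin-labelled with NuGEN Ovation kits and hybridised to one-colour Affymetrix arrays. The 5 samples were named biological replicates of 1 group, and each had 1 array. Signals of different probe sets were not set against each other.

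The deposited values were 1 number per probe set and array on a log2 scale. The log base is not stated; it was inferred from the values, which ran from 2.46 to 15.24, since powers of 2 of these stay within the range of a 16-bit scanner and powers of 10 would not. The software, the background correction and the normalization between arrays are not given in the sources used here. The 5 columns had nearly the same quantiles (medians 7.17, 7.14, 7.17, 7.12 and 7.19), so the values were used as deposited, with quantile normalization as an alternative. No scanner files were used here, so saturation and spot quality could not be checked.

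Probe sets were named through a platform annotation of 2016. Of 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 were unnamed here; the last 2 kinds were left out. For 34754 of the 34958 the gene identifier was found in a reference gene table, and 0 symbols differed between the annotation and that table, so older names can remain. Each of 18194 genes was represented by the probe set with the highest mean over the arrays. That rule favours probe sets with signal and can pick one that hybridises to related transcripts. No coordinates are given, since no genome build is named for the probes.

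Gene lists (28, with 534 distinct genes) were written before the data were examined, and 29 of their genes had no probe set with a single symbol here. They cover the 2 cell identities named in the labels, other lung epithelium, mesenchymal, endothelial, immune, erythroid and mesothelial cells, and cell cycle, lipid, stress, defence and signalling programmes. The lists for neutrophils, cardiac muscle and B lymphocytes were added after the data had been seen.

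The background of each array was the 95th percentile of 74 chemosensory receptor genes, which lung cells are not expected to use. Values minus that background were fitted with an intercept in limma 3.58.1 (R 4.3.3; lmFit, eBayes with a mean-variance trend). A gene was called above background at a Benjamini-Hochberg adjusted p under 0.05 in the one-sided moderated test; 2 of the 74 receptor genes were called too. Each list was compared with the other measured genes by Fisher's exact test, two-sided, adjusted over the 28 lists. Genes are not independent, and these tests compare lists on these arrays only.

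Spread between replicates was tested per gene as the variance over the 5 arrays divided by the variance fitted by limma (trend, robust) for genes of that signal, with a one-sided F test on 4 and 3.85 degrees of freedom. For lists with at least 5 members above background (27), the score of an array was the mean of the gene-centred values less the median over all genes above background. The SD of the 5 scores was compared with that of 10000 random lists of the same size, matched on deciles of mean signal, and the one-sided permutation p was adjusted over the 27 lists. Because scores are centred on the array median, they show change relative to other genes. Agreement was Pearson's r across genes for each of 10 pairs of arrays. Arrays give no counts, so the number of arrays sets the precision.

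The background, spread and list score tests were run on simulated data, with 200 genes changed in the background and spread tests and 5 lists of 20 genes in the list test. The background test recovered 74% of genes 0.5 log2 units and 96% of genes 1 log2 unit above background, with 6 genes at background called. The spread test recovered 0% of genes with SD raised 5 times (92% at an unadjusted p under 0.05) and 68% with SD raised 20 times, with 3 unchanged genes called. The list test recovered 5 of 5 lists given a common deviation of SD 0.3 and called 1 of 35 unchanged lists. The simulated genes were independent, so this does not give the rate of calls for genes that vary together.

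Genes were named by a rule fixed before the data were examined: the first 4 members of each list with a probe set (8 for alveolar type 2 and ciliated markers), the members on the minority side of the background call where there were 5 or fewer, genes past the spread threshold, Nkx2-1, Xist and the Y-linked genes, and, for lists that differed together, the 3 members with the largest range. The text gives values for most of these and not for all. Any other gene is said to have been chosen after its values were seen. The alternatives were other background percentiles (90 and 99), organ-restricted genes as background, the median over probe sets, no probe sets of types that can cross-hybridise, quantile normalization or median centring, filters on low signal, other variance fits, a median list score and leaving out each replicate. Plots were drawn with matplotlib 3.10.9.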

Results

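RNA was profiled from GFP-positive cells isolated by flow cytometry from the lungs of SPC-GFP mouse pups on postnatal day 2. SPC is the usual abbreviation of surfactant protein C, the product of Sftpc and the classical marker of alveolar type 2 cells, which line the air sacs and secrete surfactant. The pups came from matings of the transgenic line with outbred ICR mice. There were 5 biological replicates with 1 array each, all in 1 group, so no treatment, age or genotype could be compared. The labels name the sorted cells in 2 ways: titles and source say alveolar type 2 cells, and the design text says ciliated cells. They do not say whether a replicate came from 1 pup or from a pool. The limma and F test p-values measure the spread between these 5 samples, and the Fisher and permutation p-values compare lists of genes on these arrays only. The comparisons were which cell type markers and gene programmes gave a signal above background, and which of them differed between the replicates.

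The arrays carried 45101 probe sets, of which 34958 had 1 gene symbol and represented 18194 genes. Deposited values were taken as log2 signals, a scale inferred from their range, with medians of 7.12 to 7.19 per array. Gene values are given as mean ± SD over the 5 arrays (n = 5). Each gene is represented by its probe set of highest mean, and levels were not ranked between genes. Background was the 95th percentile of 74 chemosensory receptor genes and lay at 5.13, 5.21, 5.20, 5.32 and 5.22 in replicates 1 to 5. Of 18120 genes outside that set, 14169 (78.2%) lay above background by limma's one-sided moderated test at a Benjamini-Hochberg adjusted p under 0.05. The number of arrays limits the precision of all of these values.

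Alveolar type 2 markers gave signals above background in all 5 replicates. Sftpc was measured at 14.67 ± 0.053, the surfactant protein genes Sftpb and Sftpa1 at 14.13 ± 0.077 and 14.71 ± 0.042, and Abca3, the lipid transporter of lamellar bodies, at 14.39 ± 0.072. Sftpd was measured at 14.27 ± 0.077, the phosphate transporter Slc34a2 at 13.87 ± 0.12, the protease Napsa at 13.69 ± 0.053 and Lpcat1, an enzyme of surfactant lipid synthesis, at 14.11 ± 0.092. All 23 measured markers lay above background, with means from 12.47 to 14.71 and a median SD of 0.082; Lamp3 and Sfta2 were not analysed here. Means of 10 of the 23 exceeded 14, close to the highest value on each array (15.13 to 15.24), where the signal has little room to differ. The share of markers above background was 100% against 78.2% of the other genes (Fisher's exact test, two-sided, adjusted p = 0.0273 over 28 lists). Adjusted over the list alone, 23 were also called.

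Ciliated cell markers were measured in the same samples. The ciliogenesis regulator Foxj1 was measured at 7.91 ± 0.61, the axoneme genes Ccdc39 and Rsph1 at 9.75 ± 0.51 and 9.33 ± 0.79, and Tekt1, a tektin of the ciliary microtubules, at 9.41 ± 0.64. The axonemal dynein genes Dnah9, Dnah11 and Dnaic1 (now Dnai1) had 8.02 ± 0.78, 9.61 ± 0.34 and 6.66 ± 0.83. Of 37 measured ciliated markers, 35 lay above background (94.6% against 78.2% of other genes, Fisher's exact test, adjusted p = 0.0459), and 35 adjusted over the list alone. The exceptions were Dnah5 (5.46 ± 0.36, limma adjusted p = 0.0866) and Spag17 (4.71 ± 0.76, adjusted p = 1); Dnah5 was called without replicate 3 or 4 (limma adjusted p = 0.0391 and 0.0449). The median SD of the list was 0.656. The shares of the 2 marker lists above background differed by 5.41 percentage points, and Fisher's exact test found no difference (two-sided p = 0.519). Both shares lay near their upper limit at a background that 78.2% of other genes passed. The test therefore cannot decide between the 2 identities and does not show that the labels' 2 names are equally supported. The sort by GFP in SPC-GFP pups goes with the name alveolar type 2. With 43 genes restricted to other organs as background, at 7.20 to 7.68 per array, the count stayed at 23 of 23 for alveolar type 2 markers and was 30 of 37 for ciliated markers. The difference was then 18.9 percentage points (Fisher's exact p = 0.0370), and Dnaic1 lay below that background. As a 95th percentile of 43 genes, that background rests on the few highest of them. Some, such as the pituitary hormone gene Tshb, gave signal themselves, so the difference depends on this choice of background.

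**Figure D1:**
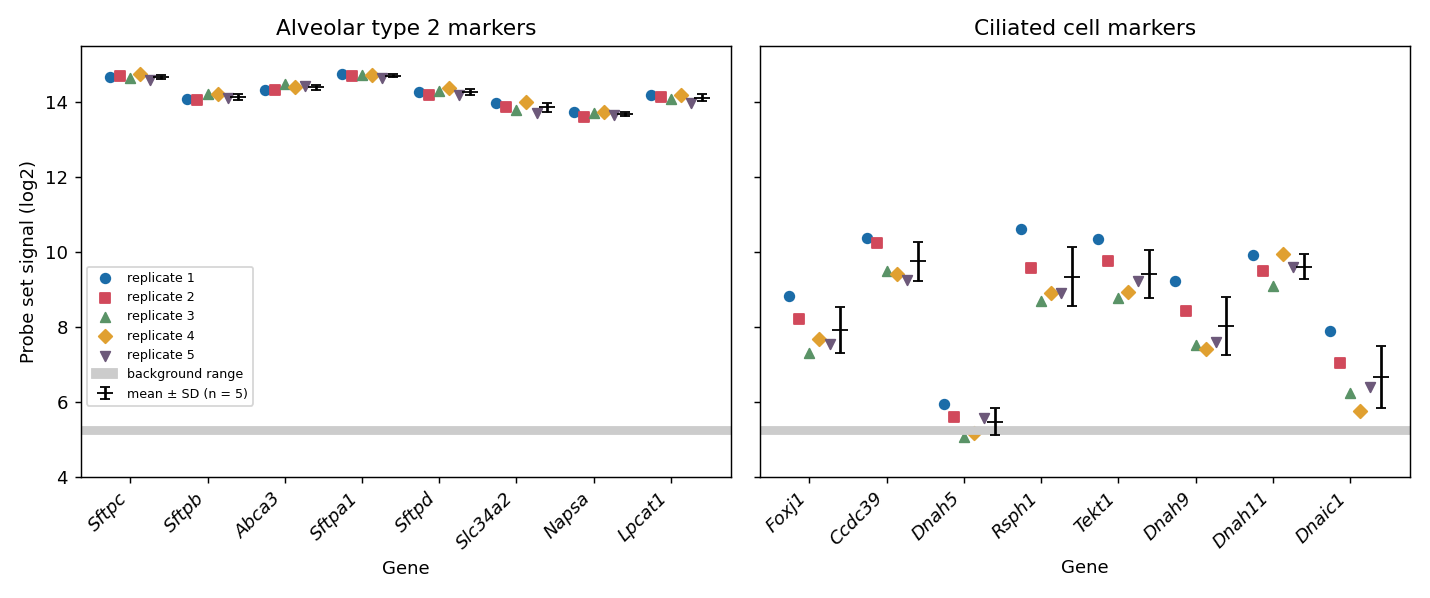
Log2 signal (vertical axis) of the first 8 alveolar type 2 markers and the first 8 ciliated markers of each list, with 1 point per replicate, the mean and an SD bar (n = 5), and the background of the arrays as a grey band. Alveolar type 2 markers lie at 13.69 to 14.71, the replicates of Rsph1 run from 8.68 to 10.62 and Dnah5 lies beside the background at 5.46.

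Ciliated markers differed together between the replicates. The list score of an array is the mean deviation of a list's members above background from their own means, less the median deviation of all genes above background. For the 35 ciliated genes it was 0.91, 0.27, −0.40, −0.42 and −0.36 in replicates 1 to 5, a range of 1.33 log2 units or 2.52-fold. Replicate 1 was highest in 32 of the 35 genes and replicate 2 second in 29. Cfap206, a ciliary gene, read 9.48, 8.26, 7.41, 7.26 and 7.27 in replicates 1 to 5, and Spag6l, a component of the axoneme's central pair, read 10.03, 9.11, 7.86, 8.05 and 8.28. Tppp3, a tubulin-binding gene chosen after its values were seen, went the other way, with 12.45 in replicate 1 and 12.80 in replicate 2. The SD of the 5 scores was 0.586, against a median of 0.051 for 10000 random lists matched on signal (permutation p = 1e-04, the smallest they can give, adjusted p = 0.00045). Without replicate 1 the SD was 0.337 and still passed (adjusted p = 0.00045). Adjusted over the list alone, 22 of the 35 genes passed the test of single-gene spread; over all genes, 0 did. The 5 hybridisation control probe sets of bacterial bioB and bioC were also highest in replicate 1, at 12.73 against 11.78 to 11.98 in the other replicates.

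The alveolar type 2 list also differed together between the replicates. Its scores were 0.01, −0.04, 0.03, 0.09 and −0.09, a range of 0.18 log2 units or 1.13-fold, with the highest value in replicate 4 for 16 of 23 genes and the lowest in replicate 5 for 16 (SD 0.068, permutation adjusted p = 0.0027). Since many of these genes lie near the top of the scale, the width of this range was not set against that of other lists. Chil1, a chitinase-like gene, had 14.08 ± 0.17, the fatty acid binding protein gene Fabp5 13.91 ± 0.14 and the transcription factor gene Etv5 12.96 ± 0.13.

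Alveolar type 1 markers, of the flat cells through which gas is exchanged, were all above background in the same sort. Ager was measured at 14.68 ± 0.015, Pdpn at 13.24 ± 0.091, the homeodomain gene Hopx at 13.26 ± 0.12 and the water channel gene Aqp5 at 13.52 ± 0.21. All 22 lay above background (Fisher's exact adjusted p = 0.0309). They also moved together, with scores of −0.21, 0.14, 0.12, −0.08 and 0.03, and 18 of the 22 genes were lowest in replicate 1 (SD 0.146, permutation adjusted p = 0.00045). Rtkn2 read 11.07, 11.79, 12.01, 11.18 and 11.89 in replicates 1 to 5, Spock2 12.57, 13.24, 13.43, 12.83 and 13.31 and Igfbp2 10.84, 11.54, 11.30, 11.02 and 11.40.

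Club and secretory cell markers of the airways were measured as well. Scgb1a1, the main secretory protein gene of club cells, had 14.50 ± 0.086, Scgb3a2 14.31 ± 0.10 and the cytochrome gene Cyp2f2 13.16 ± 0.14. The airway secretoglobin gene Scgb3a1 varied most of the list, at 8.50, 10.37, 6.61, 8.77 and 11.19 in replicates 1 to 5, a 23.9-fold range. It was the 1 gene of the list that passed the spread test when adjusted over the list alone, and it did not pass over all genes. In total 17 of 18 markers lay above background (adjusted p = 0.198), and 18 adjusted over the list alone; the exception was Reg3g (6.15 ± 1.63, adjusted p = 0.0520), which was called without replicate 3 (limma adjusted p = 0.00300). The list moved together, with scores of −0.17, 0.29, −0.25, 0.02 and 0.11 (SD 0.217, permutation adjusted p = 0.00045). Bpifa1 and Muc5b, made by secretory cells, read 7.01, 5.18, 5.39, 7.33 and 5.07 and 6.25, 7.02, 6.51, 6.46 and 8.03, and their means lay below the organ-restricted background. Bpifa1 was not called without replicate 1 or 4 (limma adjusted p = 0.0993 and 0.118).

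Most basal and neuroendocrine markers lay near the floor of the arrays. Krt15 had 9.81 ± 0.52, while Trp63, the transcription factor gene of basal cells, had 5.97 ± 0.38 and Krt5 6.68 ± 0.31. Above background were 7 of 9 basal genes (adjusted p = 1; not Krt14 at 5.43 ± 0.29 and Krt17 at 4.09 ± 0.20). Krt14 was called without replicate 3 or 5 (limma adjusted p = 0.0384 and 0.0496). Of 12 neuroendocrine genes 8 were above it (adjusted p = 0.391; not Insm1 at 4.33 ± 0.74, Neurod1 at 5.24 ± 0.23, Snap25 at 4.83 ± 0.54 and Scg2 at 5.05 ± 0.67). The secretory granule genes Chga and Chgb had 6.18 ± 0.26 and 6.48 ± 0.35, the synaptic vesicle gene Syp 6.18 ± 0.43 and Resp18 7.27 ± 0.82. With organ-restricted genes as background the counts were 3 of 9 and 2 of 12, and Trp63, Krt5, Chga, Chgb, Syp and Resp18 were among those below it. The neuroendocrine scores were 0.51, −0.04, −0.29, −0.23 and 0.06 (SD 0.316, permutation adjusted p = 0.00685), a call that rested on replicate 1 (adjusted p = 0.268 without it). Ciliated markers (score 0.91) and the bioB and bioC controls (12.73 against 11.78 to 11.98) were highest in replicate 1 as well. Resp18 read 8.58, 7.47, 6.42, 6.80 and 7.12 in replicates 1 to 5 and Pcsk1, a prohormone convertase gene, 6.40, 5.33, 5.55, 5.02 and 5.90; Pcsk1 was not called without replicate 1, 3 or 5 (limma adjusted p = 0.138, 0.0518 and 0.0863). Basal scores ran from −0.26 to 0.15 and did not pass (adjusted p = 0.223), except without replicates 1 and 3 together (0.0420).

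Genes of the epithelium as a whole and of distal tip progenitors had list scores that differed little between replicates. The adhesion genes Epcam and Cdh1 had 13.45 ± 0.037 and 13.42 ± 0.080, the keratin gene Krt8 13.18 ± 0.031, and Nkx2-1, the transcription factor gene of lung epithelium, 9.22 ± 0.029. All 23 pan-epithelial genes lay above background (adjusted p = 0.0273), and their scores spanned 0.07 log2 units (permutation adjusted p = 0.748). Among the genes of the growing lung tip, Sox9 had 11.04 ± 0.091, Id2 13.40 ± 0.14, Mycn 10.79 ± 0.10 and Etv4 6.23 ± 0.16. Of 14 measured tip genes 13 lay above background (adjusted p = 0.399), the exception being Lin28b at 2.90 ± 0.14, and their scores also spanned 0.07 log2 units (permutation adjusted p = 0.853). Etv4 lay below the organ-restricted background.

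Transcripts of mesenchymal cells were present and differed between replicates. The collagen genes Col1a1 and Col3a1 had 12.96 ± 0.22 and 13.04 ± 0.31, the growth factor receptor gene Pdgfra 9.52 ± 0.34 and the smooth muscle actin gene Acta2 12.48 ± 0.43. Acta2 rested on a probe set of a type that can hybridise to related transcripts; its other 2 probe sets averaged 4.66 and 5.33, at background. Of 28 fibroblast, myofibroblast and smooth muscle genes, 26 lay above background (adjusted p = 0.116), but not Lum (5.42 ± 0.94) or Fgf10 (5.05 ± 0.42). Without replicate 3, where it was lowest, Lum was called (limma adjusted p = 0.00130). Scores were −0.03, 0.31, −0.48, −0.14 and 0.35, a range of 0.84 log2 units or 1.79-fold. Replicate 3 was lowest in 18 of the 26 genes and replicate 5 highest in 15 (SD 0.344, permutation adjusted p = 0.00045). Replicate 3 also had the largest 3′ to 5′ differences of the Gapdh and Actb control probe sets (1.67, and 0.845 against 0.542 to 0.599), and a list of cardiac muscle genes added after the data had been seen was lowest there and highest in replicate 5 as well (−0.56 and 0.35). Dcn, a proteoglycan gene of the matrix, read 8.90, 9.40, 7.05, 8.65 and 8.65 in replicates 1 to 5, Mfap5 9.32, 9.63, 7.77, 8.76 and 9.59 and Tagln, a smooth muscle gene, 11.48, 12.07, 10.99, 11.31 and 12.25. Adjusted over the list alone, 13 genes passed the spread test and over all genes 0 did.

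Endothelial and immune transcripts were found as well. The endothelial junction genes Pecam1 and Cdh5 had 9.82 ± 0.17 and 10.10 ± 0.13, and the VEGF receptor genes Kdr and Flt1 10.47 ± 0.14 and 9.12 ± 0.32. All 23 endothelial genes lay above background (adjusted p = 0.0273), and their scores of 0.10, −0.14, −0.15, 0.05 and 0.14 spanned 1.22-fold (SD 0.135, permutation adjusted p = 0.00515). Ptprc, which encodes the leukocyte antigen CD45, had 9.36 ± 0.30, Laptm5 12.10 ± 0.36, Csf1r, the receptor gene of macrophages, 12.30 ± 0.28, and the alveolar macrophage receptor gene Marco 9.11 ± 0.65. The probe set of Laptm5 is of a type that can hybridise to other transcripts, and its other 4 probe sets averaged 9.43, 9.63, 4.84 and 4.27. Of 27 immune genes 26 lay above background (adjusted p = 0.0459), and the exception was Itgam (4.62 ± 0.43). Immune scores were 0.06, 0.05, −0.58, 0.18 and 0.30, with 21 of the 26 genes lowest in replicate 3, where the fibroblast and cardiac lists were lowest and the 3′ to 5′ differences largest too (SD 0.341, permutation adjusted p = 0.00045). Without replicate 3 the SD was 0.116 and still passed (adjusted p = 0.0149). The calprotectin genes S100a8 and S100a9, abundant in neutrophils, read 12.93, 11.82, 10.93, 12.86 and 12.26 and 13.54, 12.58, 11.83, 13.46 and 12.96 in replicates 1 to 5. These were the 2 immune genes that passed the spread test when adjusted over the list alone.

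Erythroid and mesothelial lists were small and mostly near the floor. Among erythroid genes, Alas2, the first enzyme of heme synthesis in red cells, had 9.37 ± 0.40 and the membrane transporter gene Slc4a1 8.30 ± 0.75, whereas Hba-a1 (4.11 ± 0.29) and Epb42 (4.80 ± 0.37) lay below background. Hba-a1 rested on 1 probe set, and probe sets with several symbols were left out, so its value does not show that globin RNA was absent. The means of the list ran from 3.11 to 12.34. In total 8 of 14 were above it (adjusted p = 0.157), 5 with the 99th percentile and 4 with organ-restricted genes as background. Erythroid scores were 0.24, −0.18, −0.06, 0.16 and −0.16 (SD 0.191, permutation adjusted p = 0.0451), a call lost without replicate 1, 2, 4 or 5 (highest adjusted p = 0.127), with the median over probe sets (0.0502), without probe sets of types that can cross-hybridise (0.0716) and with no filter on low signal (0.0666). Msln, a surface protein gene of mesothelium, had 11.73 ± 0.18, and 5 of 9 mesothelial genes lay above background (adjusted p = 0.173), 3 with organ-restricted genes. Those below were Wt1 (5.52 ± 0.64), Lrrn4 (4.56 ± 0.13), Muc16 (4.58 ± 0.78) and Bnc1 (4.77 ± 0.68), of which Wt1 was called without replicate 3 or 5 (limma adjusted p = 0.0315 and 0.0266). Mesothelial scores were −0.04, 0.42, −0.19, 0.22 and −0.40 (SD 0.325, permutation adjusted p = 0.0195), a call lost without replicate 2 (adjusted p = 0.0798), without probe sets of types that can cross-hybridise (0.0923) and with the median over list members (0.0521). Upk3b read 8.84, 8.69, 7.97, 9.46 and 7.02 in replicates 1 to 5 and Gpm6a 9.54, 11.32, 9.82, 10.04 and 9.80. These 2 genes passed the spread test when adjusted over the list alone.

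Cell cycle genes were all measured above background and set replicates 1 and 4 apart from the other 3. The proliferation marker Mki67 read 11.86, 10.73, 10.40, 11.85 and 10.92 in replicates 1 to 5, and Top2a, the topoisomerase of dividing cells, 11.51, 10.43, 10.07, 11.33 and 10.26. Cdk1, the mitotic kinase, read 11.62, 10.40, 9.99, 11.31 and 10.34, and the cyclin gene Ccnb2 10.40, 9.29, 8.90, 10.13 and 9.13. Ube2c, which serves the degradation of mitotic cyclins, had a 3.81-fold range, the spindle gene Tpx2 4.14-fold and the centromere gene Cenpf 4.07-fold. All 37 genes lay above background (adjusted p = 0.00517). Scores were 0.63, −0.20, −0.56, 0.46 and −0.32, a range of 1.19 log2 units or 2.28-fold. In 34 of the 37 genes replicates 1 and 4 both lay above replicates 2, 3 and 5 (SD 0.516, permutation adjusted p = 0.00045). Adjusted over the list alone, 18 genes passed the spread test and over all genes 0 did. The 12 spiked polyadenylated control probe sets were lowest in the same replicates, at 8.18 and 8.06 in replicates 1 and 4 against 9.33, 8.92 and 8.64 in replicates 2, 3 and 5. The 3′ to 5′ difference of the Gapdh control probe sets was also smallest there, at 1.27 and 1.39 against 1.52, 1.67 and 1.60, but that of Actb was not, at 0.599 and 0.547 against 0.542, 0.845 and 0.560. S100a8 and S100a9 were likewise highest in replicates 1 and 4, as was a neutrophil list added after the data had been seen (scores 0.49, −0.30, −0.86, 0.51 and 0.16). Of the lists that differed together, 7 others also had their highest scores in replicates 1 and 4: erythroid, immediate early, heat shock, endoplasmic reticulum stress, glucocorticoid, hypoxia and FGF target genes. For erythroid, heat shock and hypoxia genes, replicate 4 scored 0.16, 0.20 and 0.10. The highest of replicates 2, 3 and 5 scored −0.06, −0.03 and −0.07. Replicate 4 scored 0.045, 0.039, 0.075 and −0.002 for immediate early, endoplasmic reticulum stress, FGF and glucocorticoid genes. The next replicate was close, at 0.033, 0.035, 0.068 and −0.047. Of all planned lists scored, 10 had replicates 1 and 4 highest, against 2.7 expected by chance, but genes are not independent.

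Genes of lipid synthesis, which supplies surfactant, mostly lay above background. Fasn, the fatty acid synthase gene, had 13.23 ± 0.11, the desaturase gene Scd1 14.09 ± 0.18, Acaca 12.14 ± 0.16 and the citrate lyase gene Acly 13.61 ± 0.081. Of 28 fatty acid and phospholipid synthesis genes 27 lay above background (adjusted p = 0.0459), the exception being Pnpla3 (5.29 ± 0.18). Their scores spanned 1.14-fold (SD 0.081, permutation adjusted p = 0.0155), with Dgat2, the last enzyme of triglyceride synthesis, at 10.45, 9.40, 9.39, 10.36 and 9.71 in replicates 1 to 5. Elovl6 had 7.10 ± 0.37 and lay below the organ-restricted background. In cholesterol synthesis, Hmgcs1 had 14.32 ± 0.052, Sqle 10.75 ± 0.16, Lss 10.13 ± 0.18 and Fdft1 11.51 ± 0.19. All 20 measured cholesterol genes lay above background (adjusted p = 0.0431). Scores of the cholesterol list spanned 1.17-fold (SD 0.079, permutation adjusted p = 0.0223), a call lost without replicate 3 (adjusted p = 0.0581) or replicate 5 (0.345) and with the median over probe sets (0.0510).

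Immediate early and heat shock genes, which respond within minutes to stimulation and to heat or proteotoxic stress, all lay above background. Fos had 13.97 ± 0.094, Jun 13.41 ± 0.14, Egr1 13.85 ± 0.10 and Atf3 12.93 ± 0.18, and all 24 immediate early genes lay above background (adjusted p = 0.0273). Their scores were lowest in replicate 5, at −0.18 against 0.01 to 0.11 in the others (SD 0.111, permutation adjusted p = 0.0027), and the call was lost without it (adjusted p = 0.308). Egr3 read 8.19, 7.14, 7.63, 7.80 and 6.72 in replicates 1 to 5. All 14 heat shock genes lay above background (adjusted p = 0.0996), with Hspa1b at 13.19 ± 0.33, Hsph1 at 12.57 ± 0.25 and the co-chaperone gene Dnajb1 at 12.08 ± 0.27. Heat shock scores were 0.18, −0.03, −0.08, 0.20 and −0.26, a range of 1.38-fold (SD 0.193, permutation adjusted p = 0.000771), with the highest values in replicates 1 and 4, where the polyadenylated controls were lowest and neutrophil genes highest. The inducible chaperone gene Hspa1a read 10.33, 9.39, 9.48, 10.67 and 8.66 and the cytosolic chaperone gene Hsp90aa1 13.06, 12.76, 12.29, 13.12 and 12.25. Adjusted over the list alone, 3 heat shock genes passed the spread test.

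Genes of endoplasmic reticulum stress, glucocorticoid response and hypoxia were above background in all measured members. Hspa5, the chaperone BiP, had 13.17 ± 0.028, Ddit3 10.09 ± 0.058, Atf4 13.43 ± 0.048 and Xbp1 12.13 ± 0.082, and 18 of 18 such genes were above background (adjusted p = 0.0459). Their scores were highest in replicate 1 and lowest in replicate 3, 1.18-fold apart (SD 0.104, permutation adjusted p = 0.0142); Chac1 had 5.77 ± 0.53 and lay below background when set by the 99th percentile or by organ-restricted genes. Of the glucocorticoid-responsive genes 16 of 16 were above background (adjusted p = 0.0678), with Tsc22d3 at 11.64 ± 0.093, Fkbp5 at 8.61 ± 0.27 and Per1 at 10.16 ± 0.26. The glucocorticoid scores were highest in replicate 1, at 0.21, with the other 4 below 0 (SD 0.122, permutation adjusted p = 0.00653), and the call was lost without it (adjusted p = 0.467). Zbtb16 read 8.62, 7.63, 7.07, 7.26 and 7.41 in replicates 1 to 5. In the hypoxia list 15 of 15 genes were above background (adjusted p = 0.0996), with Vegfa at 11.98 ± 0.28, the glucose transporter gene Slc2a1 at 12.47 ± 0.19 and Ldha at 13.36 ± 0.064. Hypoxia scores were 0.19, −0.07, −0.12, 0.10 and −0.09 (SD 0.136, permutation adjusted p = 0.00926), again highest in replicates 1 and 4 as were neutrophil genes, and the peptide hormone gene Adm read 11.22, 10.78, 10.31, 11.26 and 10.73.

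Antigen presentation and defence genes were measured in the sort too. Cd74, the invariant chain of MHC class II, had 14.24 ± 0.14, H2-Aa 12.83 ± 0.13 and H2-Ab1 12.41 ± 0.22, and all 6 class II genes lay above background (adjusted p = 0.409). Class II scores were lowest in replicate 2, at −0.28 against −0.01 to 0.18 in the others (SD 0.173, permutation adjusted p = 0.0222), a call lost without replicate 2 (adjusted p = 0.269). H2-Eb1 read 11.89, 11.43, 12.12, 12.20 and 12.30 in replicates 1 to 5. Of the defence genes 16 of 17 lay above background (adjusted p = 0.198; not Cxcl5 at 5.20 ± 0.70), among them Lcn2, which binds bacterial siderophores, at 13.66 ± 0.19, and the chemokine genes Cxcl1 and Cxcl2 at 11.04 ± 0.51 and 11.89 ± 0.17. Their scores were 0.11, −0.14, −0.28, 0.21 and 0.12 (SD 0.205, permutation adjusted p = 0.0027), lowest in replicates 3 and 2 as were those of the neutrophil genes. The acute phase gene Saa3 read 10.61, 10.44, 9.40, 10.35 and 12.24 and the chemokine gene Ccl20 6.36, 6.78, 6.03, 7.58 and 8.63, and 4 genes passed the spread test when adjusted over the list alone. All 21 interferon-responsive genes lay above background (adjusted p = 0.0309), with Irf7 at 8.18 ± 0.11, Ifit1 at 7.34 ± 0.17, Ifit2 at 9.71 ± 0.46 and Ifit3 at 9.40 ± 0.53. Interferon scores did not pass (SD 0.108, permutation adjusted p = 0.109), except without replicate 3 (adjusted p = 0.0445), while without replicate 1 the SD fell to 0.035 (adjusted p = 0.853); Isg15 was not analysed here.

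Targets of the FGF, Wnt and Notch pathways, which pattern the growing lung, were measured with small differences between replicates. The FGF feedback genes Spry1, Spry2 and Spry4 had 12.44 ± 0.13, 13.33 ± 0.12 and 9.21 ± 0.14, and Dusp6 12.24 ± 0.14. All 11 FGF targets lay above background (adjusted p = 0.198). Their scores spanned 1.17-fold (SD 0.110, permutation adjusted p = 0.0344), a call lost without replicate 2 (adjusted p = 0.0759) or replicate 5 (0.115) and with the median over probe sets (0.0809); Dusp4 had 10.69 ± 0.28. Axin2, a Wnt feedback gene, had 10.97 ± 0.11, Lef1 9.39 ± 0.19 and Nkd1 10.56 ± 0.21, and 10 of 11 Wnt targets lay above background (adjusted p = 0.519), the exception being Lgr5 (5.09 ± 0.78). Notch1 had 11.94 ± 0.18, Notch2 13.15 ± 0.12 and the target genes Hes1 and Hey1 10.51 ± 0.22 and 10.27 ± 0.41; 11 of 12 Notch genes lay above background (adjusted p = 0.519), but not Dtx1 (5.44 ± 0.39), which was called without replicate 4 (limma adjusted p = 0.0270). Neither Wnt nor Notch scores passed (permutation adjusted p = 0.188 and 0.392), except Wnt scores with no filter on low signal (0.0251).

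Xist and Eif2s3y had the largest variance ratios of all genes tested for spread between the replicates. Xist, the RNA that silences the second X chromosome of female cells, read 12.49, 13.21, 7.64, 12.70 and 12.68 in replicates 1 to 5, a 47.5-fold range with replicate 3 lowest. The Y-linked translation factor gene Eif2s3y read 12.02, 5.40, 12.71, 12.15 and 11.72, a range of at least 159-fold with replicate 2 lowest and near the background. The Y-linked demethylase genes Kdm5d and Uty read 8.09, 4.77, 9.04, 8.07 and 8.04 and 7.54, 4.01, 8.62, 7.58 and 7.09, and both were lowest in replicate 2 as well. By the probe set used, Xist lay above the background of each array in all 5 replicates, but another Xist probe set read 3.31 in replicate 3, below the background of 5.20 there. In replicate 2 Kdm5d and Uty lay below the background of 5.21 and Eif2s3y at 5.40, and in the other 4 replicates all 3 Y-linked genes lay above background. All 4 genes passed the spread test when adjusted over the list alone, and 0 passed over all genes (lowest adjusted p = 0.153, for Eif2s3y and Xist). Without replicate 1, Eif2s3y and Xist passed over all genes (adjusted p = 0.0161). Ddx3y was not analysed here, and under the organ-restricted background 2 of the 4 genes lay above background.

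**Figure D2:**
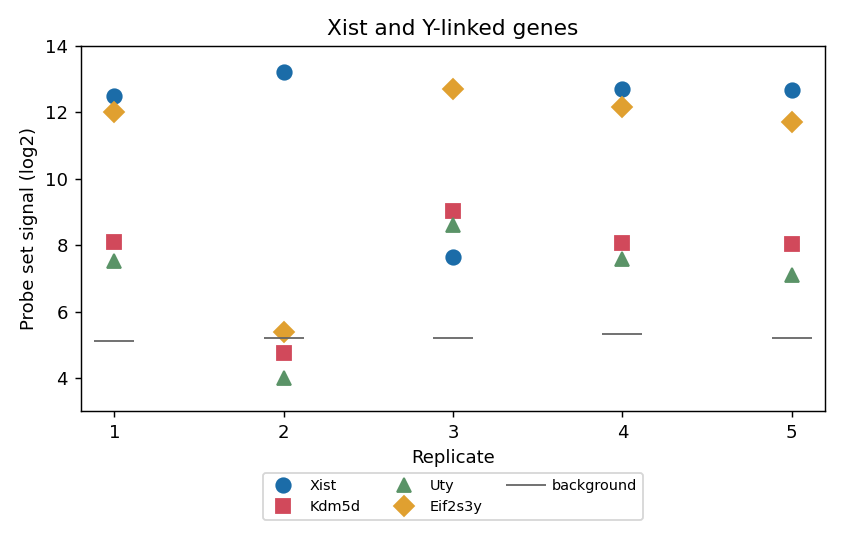
Log2 signal (vertical axis) of Xist and of the Y-linked genes Kdm5d, Uty and Eif2s3y in each of the 5 replicates (horizontal axis), with the background of each array as a dash. Xist lies at 7.64 in replicate 3, and Eif2s3y, Kdm5d and Uty lie at 5.40, 4.77 and 4.01 in replicate 2.

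The replicates were also compared across all genes. Pearson's r between pairs of arrays, across the 14171 genes above background, ran from 0.979 for replicates 1 and 3 to 0.991 for replicates 2 and 5 over 10 pairs; genes are not independent replicates, and differences in level between genes keep r high whether or not the replicates differ. No 2 arrays held the same values. The median SD per gene was 0.157. No gene passed the test of spread above the trend of genes of that signal (limma variance trend, F test, 0 of 14171 at an adjusted p under 0.05). An unadjusted p under 0.05 was found for 780 of the 14171. The variance trend and the degrees of freedom of its fit came from these same variances. A share near 0.05 was therefore built in and does not show that the replicates differed only by chance. On simulated data with 14171 genes the test recovered 0% of genes with SD raised 5 times and 68% of those raised 20 times, so a count of 0 does not show that single genes were even. Of 27 lists with at least 5 members, 21 differed together between the replicates more than random lists of matched signal. Leaving aside the alveolar type 2 list, with many genes near the top of the scale, ciliated and cell cycle genes had the widest scores of those lists, at 2.52-fold and 2.28-fold.

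**Figure D3:**
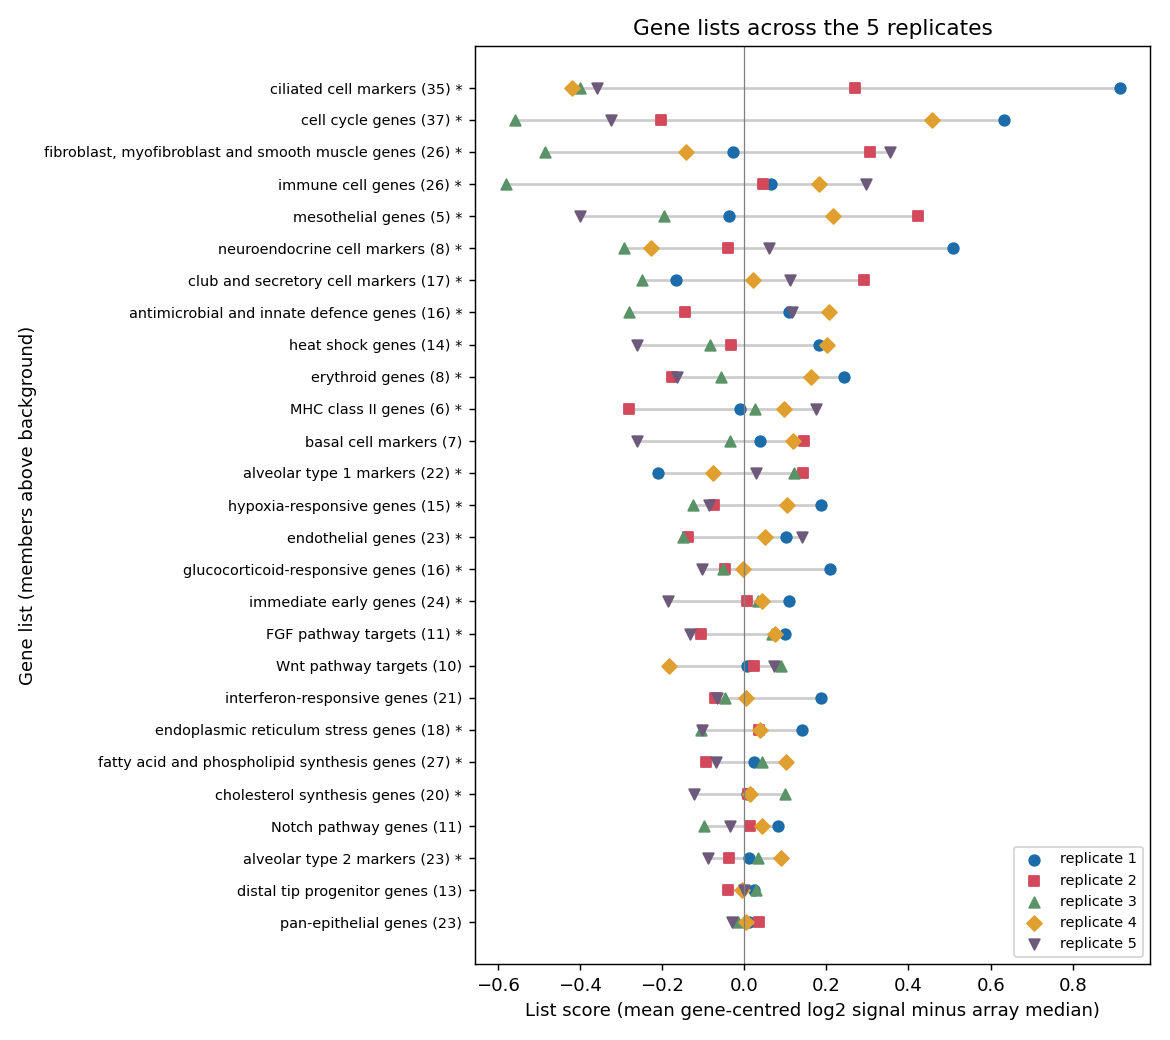
List score (horizontal axis, log2 units) of each of the 5 replicates for the 27 gene lists (vertical axis); a star marks the 21 lists with a permutation adjusted p under 0.05. Ciliated and cell cycle genes span 1.33 and 1.19 log2 units, and pan-epithelial and distal tip genes 0.07.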

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

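In 12 of 208 results (181 named genes and 27 list scores), 1 replicate lay far from the other 4 by Dixon's criterion, with a gap to the nearest replicate of more than 0.71 of the whole range. Chance alone gives about 1 in 20, or 10.4 of 208. The tests on hybridisation, on RNA input or quality, on fewer alveolar cells, on fibroblast, endothelial or immune cells and on blood cells were chosen only after the result was seen. The design has 1 group, so no biological explanation from a group was tested for any pattern.

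Replicate 3 was apart in 5 results. The immune list scored −0.58 there against 0.05 to 0.30, Lum read 3.79 against 5.61 to 6.16, and Xist 7.64 against 12.49 to 13.21. Sqle and Fdft1, of cholesterol synthesis, were highest in replicate 3, at 11.02 against 10.64 to 10.71 and 11.84 against 11.36 to 11.49. Replicate 2 was apart in 4, with Kdm5d at 4.77 against 8.04 to 9.04 and Eif2s3y at 5.40 against 11.72 to 12.71. Also in replicate 2, the mesothelial genes Gpm6a and Rspo1 were highest, at 11.32 against 9.54 to 10.05 and 7.35 against 6.55 to 6.75. Replicate 1 was apart for Neurod1, at 5.66 against 5.10 to 5.17, and for Hsph1, at 13.01 against 12.41 to 12.57. Replicate 5 was apart for Jun, at 13.17 against 13.43 to 13.52.

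Ciliated cell genes were highest together in replicate 1, with a score of 0.91. Their mean deviation there, over the 31 genes with a mean of 11 or less, was 0.96 ± 0.36 (SD). The same measure, over 4 to 17 genes per list, was −0.22 for club, 0.0063 for fibroblast, 0.12 for endothelial, 0.036 for immune, 0.038 for basal, 0.019 for mesothelial, 0.29 for erythroid, 0.51 for neuroendocrine and 0.53 for neutrophil genes. All 9 lists lay below the ciliated list (highest permutation p = 0.0034, for neuroendocrine genes). Stronger hybridisation raising all genes of that signal alike would largely be taken out by the median centring and the nearly equal array quantiles. The lists were also not matched on signal, so this comparison cannot test it. Fewer alveolar cells in the sort would not by themselves raise 1 list most, but lists near the floor need not rise alike. Alveolar type 1 genes were lowest in replicate 1 (score −0.21, 18 of 22 genes), which fewer alveolar cells of that type would also give. The alveolar type 2 and pan-epithelial lists each scored 0.01 there and were not lowered, but many type 2 genes lie near the top of the scale. Fewer alveolar cells therefore stay open as part of the pattern. The difference between the lists does not account for the rise of the neuroendocrine and neutrophil genes. Stronger hybridisation that differs between genes cannot be told apart from a change in RNA: the bioB and bioC controls of replicate 1 lay 0.75 log2 units above the next highest array, and they do not show which other genes such an effect would reach. RNA of ciliated cells remains a candidate source: 36 of 47 cilium genes outside the list, found by symbol, were highest in replicate 1. That is 76.6%, against 20% if each array were equally likely (exact binomial p = 1.11e-16), although genes are not independent. The share of all genes highest there was not determined. These genes are of the same kind as those listed, so the p-value is not independent support. Of the list, Ccno (12.01) and Dynlrb2 (12.12) were highest there too but not Tppp3 (12.45 against 12.80 in replicate 2), each chosen after its values were seen. The GFP gate should remove ciliated cells, none of the 40 listed genes is on another list, and how many of them alveolar cells also make was not determined, so alveolar cells with more cilium gene RNA stay open too.

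Cell cycle genes were 0.91 log2 units (1.87-fold) higher in replicates 1 and 4 than in the other 3. Of the 9 cell type lists, 8 rose less than the cell cycle list (members with a mean of 11 or less, highest permutation p of the 8 = 0.0072). Neutrophil genes did not. An effect of RNA input or quality that raises all genes of that signal alike would largely be taken out by the same centring. This comparison therefore cannot test it. An effect of RNA input or quality that differs between genes cannot be told apart from a change in RNA: the polyadenylated controls were lower in replicates 1 and 4 (difference −0.84), and they do not show which genes would be affected. The Gapdh 3′ to 5′ difference was smallest in these replicates too, but the Actb difference was not (0.599 and 0.547 against 0.542, 0.845 and 0.560). Against more fibroblast, endothelial or immune cells in general, the largest mean difference of these 3 lists was 0.15, compared with 0.95 for cell cycle genes (permutation p = 1e-05 for each). Members with a mean above 11 were left out of this comparison too. Among them were S100a8 (12.16) and S100a9 (12.87), which were highest in replicates 1 and 4, so it does not cover immune cells rich in those genes. More blood cells cannot be told apart from a difference in the cycling of the sorted cells. The 11 neutrophil genes differed by 0.83 in the same direction (permutation p = 0.59 for the difference from 0.91), but between replicates 5 and 2 they differed by 0.45 and the cell cycle genes by −0.12 (permutation p = 1e-05), and the erythroid genes, at 0.33, had only 4 members 2 log2 units or more above background. The GFP gate should remove blood cells, but neutrophil genes were measured, so the amount of blood cells may have differed between the replicates too. The shared order of the arrays does not show that neutrophils supplied cell cycle RNA, and these tests do not say which cells were cycling.

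Xist and the Y-linked genes were measured together in replicates 1, 4 and 5, whereas Xist was lowest in replicate 3 and the Y-linked genes in replicate 2. Against a faulty probe set, both of the 2 other Xist probe sets were also lowest in replicate 3, by at least 4.87 and by 4.42 log2 units, at 3.31 (below the background of 5.20) and 6.04. A candidate explanation is pups of both sexes in differing proportions: 4 of 4 X-linked genes known to escape inactivation were higher in replicate 2 than in replicate 3, Kdm6a by 0.28, Eif2s3x by 0.34, Kdm5c by 0.22 and Ddx3x by 0.08 (SD over the 5 arrays 0.18, 0.13, 0.090 and 0.049). Replicates 1, 4 and 5 lay between these 2 for Eif2s3x and Kdm5c but not throughout for Kdm6a and Ddx3x. Kdm6a read 10.18 and 10.25 in replicates 1 and 5 against 10.36 in replicate 3. Ddx3x read 13.38 in replicate 4 against 13.37 in replicate 2, and 13.27 in replicate 5 against 13.28 in replicate 3. With only 4 such genes and no sex in the labels, differing proportions remain a hypothesis. Xist at 12.49 to 12.70 and Eif2s3y at 11.72 to 12.15 were both high in replicates 1, 4 and 5. These values argue against cells of only 1 sex in those replicates. Pups of both sexes would mean that replicates 1, 4 and 5 held cells of more than 1 pup, which the labels neither state nor exclude.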

How the results depend on the processing

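All settings were planned except leaving out replicates 1 and 3 together, the pair with the lowest r, which was chosen after the data had been seen. The number of genes above background ran from 10870 with organ-restricted genes as background to 14796 with the 90th percentile. In all settings run, all 23 alveolar type 2 markers stayed above background. The difference between the alveolar type 2 and ciliated shares passed only with organ-restricted genes as background, at 18.9 percentage points. Of 27 lists, 17 to 21 differed together in each setting. Without replicates 1 and 3, 19 of the 21 lists were among those that passed, and without 1 replicate 17 to 20 were. Across settings a list score that had passed did so no longer in 22 of 350 values, and in 3 a list passed that had not before. The number of genes past the spread threshold was 0 in each setting and, leaving out 1 replicate, ran from 0 to 2 (Eif2s3y and Xist, without replicate 1); the number at an unadjusted p under 0.05 ran from 648 to 1016. The cause was not tested. The lowest r between arrays was 0.988 with no filter on low signal, 0.974 with the 99th percentile filter, and ran from 0.979 to 0.986 when 1 replicate was left out; the filters change which genes enter r.

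Among named genes that had been called above background, heights above background turned negative for 22 values. With organ-restricted genes as background, which lay at 7.20 to 7.68 per array against 5.13 to 5.32, they were for Dnaic1 −0.82, Trp63 −1.51, Krt5 −0.80, Chga −1.30, Chgb −0.996, Syp −1.30, Resp18 −0.21, Pcsk1 −1.84, Etv4 −1.25, Ifit1 −0.14, Uty −0.51, Bpifa1 −1.48, Muc5b −0.63, Klf1 −1.09, Rspo1 −0.67, Elovl6 −0.38, Chac1 −1.71 and Ccl20 −0.40. With the 99th percentile they were −0.25 for Pcsk1 and −0.11 for Chac1. Syp was at −0.55 with the median over its probe sets, and Laptm5 at −0.38 without probe sets of types that can cross-hybridise; without these, Acta2 was no longer called. Other calls were lost at a height that stayed positive: with the 99th percentile Trp63, Chga, Syp and Bpifa1 (adjusted p = 0.4003, 0.0523, 0.0776 and 0.491), with organ-restricted genes Zbtb16, Egr3 and Kdm5d (0.3996, 0.744 and 0.379) and with the median over probe sets Trp63 (0.346). Calls were gained with the 90th percentile for Dnah5, Reg3g, Krt14, Neurod1, Wt1, Pnpla3 and Dtx1 (highest adjusted p = 0.0194) and with the median over probe sets for Dnah5, Reg3g and Wt1 (highest 0.0446). Acta2 and Laptm5, with heights of 7.26 and 6.89 by the probe sets used, lost their calls through the choice of probe sets. The choice of probe sets also entered the changes of Syp and Trp63 with the median over probe sets. The other calls are limited by how far the signal lies above the background used. The organ-restricted background rests on the few highest of its genes.

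Median centring of the arrays cannot move list scores, which are already centred, so it says nothing of their stability. The pseudocount alternatives were not run, because the values were already on a log scale. No paired analysis was possible because there is only 1 group.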

Other observations

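Genes of heart muscle and neutrophils were also measured in the sort, on lists added after the data had been seen and built without the genes that had drawn attention. The share of each list above background, 11 of 14, was near the 78.2% of all genes, so the counts do not set these lists apart. Of 14 measured cardiac muscle genes 11 lay above background, and their scores were 0.19, 0.09, −0.56, −0.05 and 0.35 in replicates 1 to 5, a 1.87-fold range (permutation adjusted p = 0.00015 over 3 lists). Csrp3, a muscle LIM protein gene, read 7.80, 8.19, 6.65, 7.60 and 8.95, and Myl4, an atrial myosin light chain gene, 9.61, 9.65, 8.22, 9.12 and 9.99, whereas the myosin heavy chain gene Myh7 read 12.67 ± 0.10 (SD, n = 5). Myl7 and Actc1, seen before the list was made, read 6.95 and 7.34 in replicate 3 and 10.32 and 10.42 in replicate 5. Of 14 measured neutrophil genes 11 lay above background, with scores of 0.49, −0.30, −0.86, 0.51 and 0.16, a 2.58-fold range (permutation adjusted p = 0.00015). Its gene Pglyrp1 is also on the defence list. The cytokine gene Il1b read 11.03 ± 0.50 (SD, n = 5), and the granule protein genes Camp and Ltf read 9.95 and 9.59 in replicate 4 and 7.47 and 7.43 in replicate 3. B lymphocyte genes did not differ together past the threshold (10 genes, SD 0.197, permutation adjusted p = 0.0621), with Cd79b at 10.66 ± 0.12 (SD, n = 5).

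Some single genes, chosen after their values were seen, differed between replicates by large amounts although none passed the spread test over all genes. The class I gene H2-D1 read 9.53, 12.86, 12.92, 11.54 and 12.87 in replicates 1 to 5, and the class II gene H2-Ea 9.11, 7.56, 11.33, 7.62 and 11.39. Psmc3ip, a gene of meiotic recombination, read 12.29, 11.18, 9.43, 10.39 and 9.88. Trim5 read 5.53, 8.64, 5.50, 5.10 and 8.07, and Fggy read 6.12 in replicate 4 against 9.04 to 9.16 in the others. Among genes restricted to other organs, the pituitary hormone gene Tshb read 9.12 ± 0.25 (SD, n = 5), and Ins2, an insulin gene, read 9.25 in replicate 1 against 6.24 to 6.67 in the others. No explanation was tested for any of these.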
